A study of Caenorhabditis elegans with 2 samples.

How the data were processed

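The series holds ChIP-seq of GFP-tagged SUP-37 in whole C. elegans L1 larvae, in 2 biological replicates of 1 group, with DNA fragments of 200 to 800 bp after sonication, per the labels. The replicate numbers were taken from the labels. The labels also say that the larvae were starved after bleaching and give their age as 6 hours. The description of the samples names an antibody against GFP, while their antibody label reads sup-37. No untagged strain was analysed here. The 2 control alignment files against which, per the deposited descriptions, the authors called regions were not used here, so the background at each region could be judged only through the authors' values.

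Peaks and background regions were called by the authors separately on each replicate and on the pooled alignments, in lists of 30000 regions on ce11, and the IDR-thresholded list was made from these, per the deposited descriptions. The peak caller, the aligner, their versions and the IDR cutoff are not given in the sources used here. The deposited signal of each region, in the seventh column, is the authors' own value for the strength of that region. Its scale is not stated and its median differs between lists (52.8 in the pooled list, 36.0 in replicate 1 and 23.8 in replicate 2), so it was used only to rank or describe regions within a list. The ninth deposited column holds the −log10 of the authors' q value, from 1.43 to 3.01 in the IDR list, where its median equals its highest value, so it was not used to rank. The summit is the deposited offset from the start of each region. Because the 924 IDR peaks are also the 924 strongest regions of the pooled list, ranks in those lists are the same. Most regions have the fixed width of their list (384 bp in the pooled list, 396 bp in replicate 1 and 376 bp in replicate 2), and the 94 narrower IDR peaks all rank at 218 or better. No region was shared exactly between the replicate lists, so the replicates were not copies of each other.

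The reference was WBcel235, which is the same assembly as ce11, with Ensembl release 115 gene annotation. All regions lay within the chromosome lengths of that reference, and 99.9% of 31805 annotated start codons read ATG in it. Only the 6 nuclear chromosomes held regions. Depth per library is unknown because the lists give no read counts, and no interval that would need it is given. Exact binomial (Clopper-Pearson) 95% intervals on shares of peaks or genes cover counting error only.

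Replicates were compared through the N strongest regions of each, with N set to the length of the IDR list, and summits within 200 bp counted as shared. The rank correlation was taken over IDR peaks with a region within 200 bp in both full lists, and its interval came from 1000 bootstrap draws of peaks. A summit was assigned to the first class that held it, in the order promoter (1000 bp upstream to 200 bp downstream of a protein-coding 5′ end), coding exon, 5′ UTR, 3′ UTR, intron and intergenic. Chance was taken from 1000 shuffles of the summits within their chromosomes, with two-sided permutation p-values, which can be no smaller than 0.0020. Shuffles ignore how easily a place can be mapped. The share of peaks per chromosome was compared with its share of protein-coding genes, and that of the central 50% of autosomes with its share of 5′ ends, by two-sided exact binomial tests.

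A gene counted as bound when an IDR summit fell in its promoter window. Bound genes in each of 30 lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the lists, and 18 genes were in more than 1 list. The names ram-4, opt-2, iftb-1, lin-4 and let-7 were not matched to protein-coding genes. Noncoding classes were tested by shuffles for summits within 200 bp of a gene. Words of 6 bases were counted once per window, on both strands together, in the 101 bp around each summit and around 2 flanking positions at 400 bp, and compared by Fisher's exact test. A word was called enriched at an adjusted p under 0.05 and a ratio of at least 1.5. The share of 32-mers with another copy in the reference was counted on both strands.

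The gene lists, the tests and the rule for the genes named were fixed before the data were examined. The rule took the 25 IDR peaks of highest signal with the nearest protein-coding 5′ end, sup-37 and unc-119, every gene of the PHA-1 and SUP pathway list, up to 4 genes with the strongest promoter peak in each list, and the 10 6-mers with the smallest adjusted p. Names outside the rule are marked where they occur or are neighbours that locate a peak or a stretch. The alternatives fixed beforehand were summit distances of 50 bp, overlap by 1 bp, a stricter list of the 462 strongest peaks, promoter windows of 500 to 100 bp and of 2000 to 500 bp, the nearest 5′ end within 2000 bp only, 5′ ends of all transcripts, 500 bp for noncoding genes, chromosome length as the reference share, other windows, flanks and 7-mers for the words, each replicate left out, and the 20 kb around sup-37 and unc-119 left out. Leaving out a replicate meant taking the N strongest regions of the other. IDR peaks in both top lists only, dinucleotide-preserving shuffles of each window (2 per window) and genes without tRNA, snRNA or snoRNA genes at the promoter were added after seeing the data.

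The list and word tests were checked on 924 simulated peaks. At random positions they called 0 lists and 0 words, a list given 14 bound genes was recovered with 0 other lists called, and a word put into 184 windows ranked 1, with 8 words called, most of them expected to overlap it. Random positions have neither the promoter excess nor the base composition of the real summits. The check therefore shows that strong planted signals are found, and does not measure false calls in these data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.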

Results

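SUP-37 is a C. elegans protein known from genetics as a suppressor of pha-1 mutations, which disturb pharynx development. Its binding to the genome was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in starved L1 larvae, the earliest larval stage, at 6 hours. The worms carried an integrated transgene that encodes SUP-37 fused to a GFP tag, and the description of the samples says that the precipitation used an antibody against GFP. Another label of the same samples gives the antibody as sup-37, so whether untagged SUP-37 was also captured is not settled here. The series held 1 group of 2 biological replicates, so the questions it can answer are where SUP-37 bound and how alike the replicates were. Each replicate came with a list of 30000 peak and background regions, as did the pool of both. A further list held the 924 peaks that passed the authors' irreproducible discovery rate (IDR) threshold. IDR filters on how similarly replicates rank their peaks, but an optimal set, as this list is named, can also come from pseudo-replicates (splits of the pooled reads). Which was used is not settled here. The 924 peaks are the strongest regions of the pooled list, so each need not have been selected for agreement between the replicates. All positions below are 1-based on build ce11 (WBcel235). The lists give no read counts, so the depth of each library is unknown here. Tests over peaks or genes describe these 2 libraries, since peaks and genes are not replicates. Maps of L1 open chromatin and of places bound by many unrelated factors were not analysed here, so none of the enrichments separates SUP-37 peaks from such places.

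The strongest SUP-37 peak lay upstream of rpl-3, which encodes a protein of the large ribosomal subunit. That peak (chromosome III, 3867449 to 3867689) had its summit in intergenic sequence 289 bp upstream of the 5′ end of rpl-3 and ranked 1 in both replicates, with an authors' signal of 933 in the IDR list. Of the 25 strongest peaks, 20 lay at a protein-coding promoter, defined as 1000 bp upstream to 200 bp downstream of a 5′ end. Further ribosomal protein genes in this set were rpl-20 (rank 4, in a promoter it shares with Y17G9B.5), rpl-15 (rank 9) and rpl-35 (rank 12). Chaperone genes included cct-8, which encodes a subunit of the cytosolic chaperonin (rank 14, beside Y55F3AR.2), hsp-60, the mitochondrial chaperonin (rank 15, beside Y22D7AL.10), and hsp-3, an endoplasmic reticulum chaperone of the HSP70 family (rank 25).

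The peak of rank 2 (chromosome III, 10759140 to 10759381) lay 50 bp upstream of tasp-1, and that of rank 7 (chromosome III, 12905092 to 12905298) lay 297 bp upstream of cox-5A, a subunit of cytochrome c oxidase. Peaks upstream of tag-340 (rank 6), cdc-48.1, which encodes an AAA ATPase of protein degradation (rank 11), puf-9, an RNA-binding protein gene (rank 13), tos-1 (rank 17), eelo-2 (rank 18), cmtr-1 (rank 22), F56G4.6 (rank 23) and ztf-7 (rank 24) were also at promoters, and the summit of rank 21 fell in the 5′ UTR of ints-4, an Integrator complex gene. Peaks of rank 5, 10 and 19 had egg-5, ZK1248.17 and ins-13 as the nearest protein-coding 5′ ends and lay within 200 bp of the SL2 spliced leader RNA genes sls-2.4, sls-2.1 and sls-2.2. The remaining peaks of the set were farther from protein-coding 5′ ends. The peak of rank 3 (chromosome I, 9382900 to 9383084) lay in an intron of ppfr-1, 6970 bp downstream of its 5′ end. Its summit was within 200 bp of the noncoding RNA genes anr-20 and F16A11.7. Peaks of rank 8, 16 and 20 lay in intergenic sequence 4777 bp upstream of cmd-1, the calmodulin gene, 2765 bp upstream of T04C4.3 and 1805 bp upstream of F20B6.9. The summit of rank 8 was within 200 bp of the long intergenic RNA gene linc-128.

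These strong peaks were shared between the replicates, while agreement fell along the list. All 25 ranked at 41 or better in replicate 1 and at 64 or better in replicate 2, and all of the 100 strongest IDR peaks had a summit within 200 bp among the 924 strongest regions of each replicate. Because the IDR peaks are the strongest regions of the pool of these replicates, sharing at the top of the list is partly set by that choice. Over the whole IDR list, 62.6% of peaks did so in both replicates (95% exact binomial interval 59.3 to 65.7), 16.8% in replicate 1 only, 17.1% in replicate 2 only and 3.57% in neither. Among the weaker 462 peaks the share found in both was 30.1% (25.9 to 34.5). Some peaks higher in the list also differed between replicates. The peak at the promoter shared by apb-1 and mdt-19, a Mediator subunit gene, was of rank 151 in the IDR list and 106 in replicate 2, with no region within 200 bp in replicate 1. That of hlh-11, a transcription factor gene, was of rank 377 in the IDR list, 3311 in replicate 1 and 180 in replicate 2.

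Taken without the IDR list, 62.8% of the 924 strongest regions of replicate 1 (59.6 to 65.9) had a replicate 2 counterpart, against a mean of 0.383% when positions were shuffled within chromosomes (two-sided permutation p = 0.0020, the smallest that 1000 shuffles can give). The share was 78% for the 50 strongest regions and 31.5% for the 5000 strongest. Across the 903 IDR peaks listed in both full replicate lists, the authors' signals had a Spearman correlation of 0.575 (bootstrap 95% interval 0.518 to 0.626), which is a correlation across peaks and not across samples. Asking for summits within 50 bp lowered the share of IDR peaks found in both top lists to 51.5%.

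**Figure D1:**
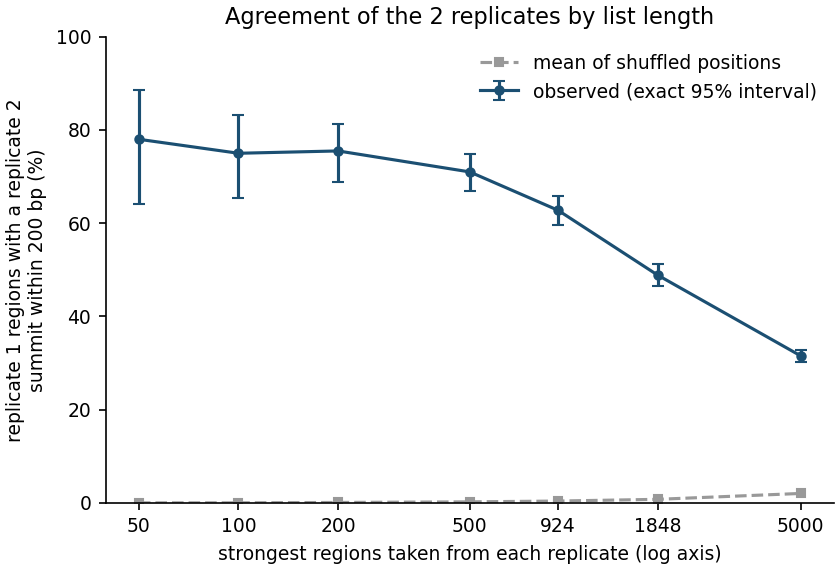
Share of the strongest regions of replicate 1 that had a replicate 2 summit within 200 bp (vertical axis, %), by the number of regions taken from each list (horizontal log axis), with exact 95% intervals. The share was 78% at 50 regions, 62.8% at 924 and 31.5% at 5000, against at most 2.01% on average in shuffles (dashed line).

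SUP-37 summits gathered upstream of genes and were rare in coding sequence. Promoters held 510 of the 924 summits (55.2%, 51.9 to 58.4), 2.62 times the mean of 21% in shuffles within chromosomes. Coding exons held 17 (1.84%) against 19.97% in shuffles, 3′ UTRs 6 (0.649%) against 2.44%, and introns 180 (19.5%) against 31.2%. Promoters and these 3 classes each had an adjusted permutation p of 0.0030 over the 6 classes. Intergenic sequence held 201 (21.8%) against 24.8% (adjusted permutation p = 0.0408), and 5′ UTRs outside the promoter windows held 10 (1.08%) against 0.560% (adjusted permutation p = 0.0559). Of the promoter summits 91.2% lay upstream of the nearest 5′ end, at a median distance of 209 bp (quartiles 126 and 365). The window reaches 1000 bp upstream and only 200 bp downstream, so most summits spread evenly over it would also lie upstream. The promoter share was 72% (62.1 to 80.5) among the 100 strongest pooled regions and 27.1% (25.7 to 28.5) among those between rank 924 and rank 5000. The share among the 924 strongest regions of a single replicate was 48.8% in replicate 1 and 55.2% in replicate 2.

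**Figure D2:**
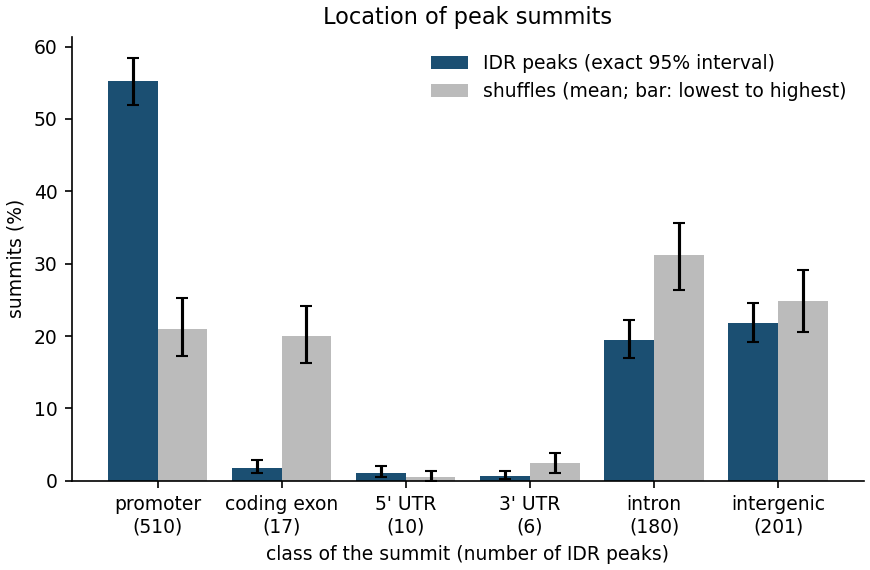
Share of summits (vertical axis, %) in each class of sequence for the 924 IDR peaks (blue, exact 95% intervals) and for 1000 shuffles of their positions within chromosomes (grey, mean with the lowest and highest shuffle). Promoters held 55.2% of summits against 21% in shuffles, and coding exons 1.84% against 19.97%.

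Chromosome III and the X chromosome held more peaks, and chromosome V fewer, than their shares of protein-coding genes. The X chromosome had 193 peaks (20.9%, 18.3 to 23.7) with 13.7% of the genes (two-sided exact binomial test, adjusted exact p = 5.33e-09 over the 6 chromosomes), and chromosome III had 172 (18.6%) with 13.2% (adjusted exact p = 7.39e-06). Chromosome V, which is rich in chemoreceptor genes, had 142 (15.4%) with 25% (adjusted exact p = 7.46e-12), and chromosome II had 134 (14.5%) with 17.3% (adjusted exact p = 0.0395). Chromosomes I (151 peaks) and IV (132) did not pass the test. Against shares of chromosome length instead, chromosome IV passed (14.3% of peaks with 17.4% of the length, adjusted exact p = 0.0184) and chromosome II did not (adjusted exact p = 0.583). On that reference the X excess was much smaller (20.9% of peaks with 17.7% of the length, adjusted exact p = 0.0184). Chromosomes III and V also passed by length (adjusted exact p = 1.14e-04 for each). Of the 58 tRNA genes with a peak nearby, most lay on the X, and its share of peaks without these was not tested. Peaks on the X were less often at promoters, with 39.9% (32.9 to 47.2) against 59.2% (55.6 to 62.8) on the autosomes (Fisher's exact test p = 2.07e-06, a comparison made after the chromosome counts were seen). The central 50% of each autosome, where essential genes are common, held 57.9% of autosomal peaks (54.2 to 61.5), against 55.7% of autosomal 5′ ends (two-sided exact p = 0.234).

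Cytosolic ribosomal protein genes were the list with the highest share of bound genes. A promoter peak lay at 687 of 19973 protein-coding genes (3.44%), more genes than promoter peaks because neighbouring genes share windows. Of the 63 genes named from the lists, 14 had another protein-coding 5′ end nearer to the peak. Among cytosolic ribosomal protein genes a promoter peak lay at 26 of 82 (31.7%, 21.9 to 42.9), 9.54 times the share in all other genes (Fisher's exact test, adjusted exact p = 4.53e-17 over 30 gene lists), led by rpl-3, rpl-20, rpl-15 and rpl-35. Translation factor genes had 9 of 37 (7.15 times, adjusted exact p = 3.35e-05), among them eif-3.C (rank 55), eif-3.B (rank 114), eef-2, the elongation factor that moves the ribosome along (rank 79), and eef-1A.2 (rank 223). Chemoreceptor genes, which are expressed mostly in sensory neurons, were bound less often than other genes, with 4 of 1286 (0.311%, a ratio of 0.0851, adjusted exact p = 4.38e-14). The 4 were srh-16, sri-5, srh-2 and srh-269. These 3 lists kept their calls under each of the 9 alternatives run for them, but the ratios moved. Assigning each peak only to its nearest 5′ end brought cytosolic ribosomal proteins down to 6.34 times and chemoreceptors up to 0.140, and the stricter list of 462 peaks brought translation factors up to 11.1 times.

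A further 6 lists passed the threshold, all with more bound genes than expected from the rest of the genome. Splicing factor genes had 7 of 31 (6.62 times, adjusted exact p = 5.30e-04), led by snr-4, prp-19, prp-8 and snr-1. Chaperone and heat shock genes had 6 of 29 (6.06 times, adjusted exact p = 0.00235), led by cct-8, hsp-60, hsp-3 and hsp-1. Mitochondrial ribosomal protein genes had 8 of 70 (3.35 times, adjusted exact p = 0.0136), led by mrps-7, mrpl-28, mrpl-12 and mrpl-23. Oxidative phosphorylation genes had 6 of 45 (3.90 times, adjusted exact p = 0.0180), led by cox-5A, mev-1, atp-1 and cox-5B. Cell cycle genes had 4 of 23 (5.08 times, adjusted exact p = 0.0261), namely efl-1, an E2F family gene (rank 179), lin-35, which encodes the retinoblastoma homologue (rank 217), cyb-1 and cye-1. RNA polymerase II and Mediator genes had 6 of 51 (3.44 times, adjusted exact p = 0.0261), led by rpb-11, mdt-19, mdt-26 and taf-4. The cell cycle call was lost with the strongest regions of replicate 2 alone (3.67 times, adjusted exact p = 0.109) or of replicate 1 alone (4.45 times, adjusted exact p = 0.0915), the mitochondrial ribosomal call with replicate 2 alone (2.01 times, adjusted exact p = 0.209) and the RNA polymerase II and Mediator call with replicate 1 alone (2.00 times, adjusted exact p = 0.406). Assigning each peak only to its nearest 5′ end within 2000 bp ended all 6 of these calls (adjusted exact p from 0.0561 to 0.405). The ratios were then 4.12 for splicing factors, 3.55 for oxidative phosphorylation, 3.30 for chaperones, 2.77 for the cell cycle, 2.28 for mitochondrial ribosomal proteins and 1.88 for RNA polymerase II and Mediator, so they ranged from near the main value to well below it. The same assignment brought 3 other lists past the threshold, namely body wall muscle (4.88 times, adjusted exact p = 0.00406), heterochronic genes (10.6 times, adjusted exact p = 0.0135) and autophagy (5.81 times, adjusted exact p = 0.0225).

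The other 21 lists did not pass. Core and linker histone genes had 7 of 80 (adjusted exact p = 0.0553), led by his-37, his-67, his-68 and his-24, and 14 of the 80 lie in a duplicated stretch of chromosome V that had no region in either replicate. A single peak, of rank 340, was counted for both his-67 and his-68, which the test treats as separate genes. Body wall muscle genes had 5 of 46 (adjusted exact p = 0.0553), led by act-4, cpn-3, clik-1 and mlc-1. Heterochronic genes, which time larval development, had 2 of 9 (lin-66 and lin-14, adjusted exact p = 0.0767), autophagy genes 3 of 22 (lgg-2, lgg-1 and epg-8, adjusted exact p = 0.0767) and proteasome genes 3 of 33 (rpn-3, rpn-11 and rpn-2, adjusted exact p = 0.194). The proteasome list passed with replicate 2 alone (4.27 times, adjusted exact p = 0.0222) but showed almost no excess with replicate 1 alone (1.03 times). With the wider window of 2000 to 500 bp, as with the nearest 5′ end, body wall muscle (adjusted exact p = 0.0160), heterochronic genes (adjusted exact p = 0.0209) and autophagy (adjusted exact p = 0.0429) passed. Single replicates were run with the main window only, where none of these lists passed with either replicate alone. With that window the heterochronic ratio fell from 6.48 times to 3.12 with replicate 2 (adjusted exact p = 0.523) and 3.78 with replicate 1 (adjusted exact p = 0.472). Body wall muscle also passed among genes without small RNA genes at the promoter, an alternative chosen after seeing the data (adjusted exact p = 0.0497). Cuticle collagens had 1 of 174 (col-63, adjusted exact p = 0.0767). Nuclear hormone receptor genes had 7 of 269 (led by nhr-47, nhr-57, nhr-48 and nhr-142), and single bound genes were found among ceh homeobox genes (1 of 63, ceh-38), ztf zinc finger genes (1 of 25, ztf-7), hlh genes (1 of 25, hlh-11), germline genes (1 of 33, cgh-1) and aminoacyl-tRNA synthetase genes (1 of 32, ears-2). No promoter peak was found at genes of pharyngeal muscle (0 of 9), pharynx transcription factors (0 of 13), gonad sheath and ovulation (0 of 14), epidermal transcription factors (0 of 13), intestine (0 of 19), pan-neuronal genes (0 of 23), starvation and insulin signalling (0 of 24) or major sperm proteins (0 of 31). With lists this short the upper 95% bound still allowed 33.6% of pharyngeal muscle genes and 24.7% of pharynx transcription factor genes. The absence also depended on the assignment in 2 of these lists. With the nearest 5′ end only, starvation and insulin signalling stood at 3.99 times (adjusted exact p = 0.115) and pharynx transcription factors at 2.45 times (adjusted exact p = 0.600). Neither passed, and the others stayed without a bound gene.

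**Figure D3:**
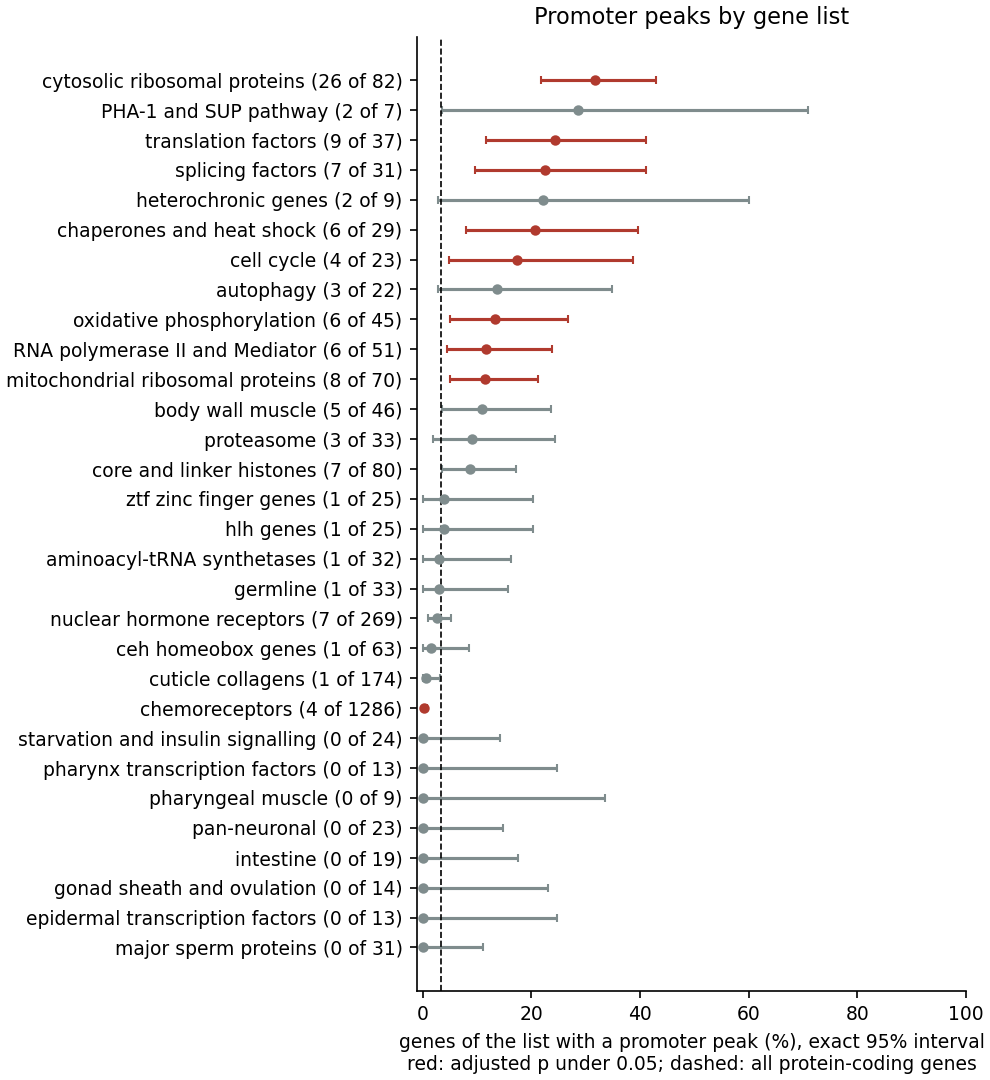
Share of the genes of each list with an IDR peak at the promoter (horizontal axis, %), with exact 95% intervals and the gene counts in brackets. Red lists passed an adjusted p of 0.05, and the dashed line marks 3.44%, the share in all protein-coding genes. Cytosolic ribosomal proteins stood at 31.7% and chemoreceptors at 0.311%.

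Among the 7 genes of the pathway in which sup-37 was found, promoter peaks lay at lin-35 and sup-35, and none lay at pha-1 or at sup-37 itself. The lin-35 peak (chromosome I, 5807225 to 5807608) was 292 bp upstream of the 5′ end, in a promoter shared with vps-51, whose 5′ end is nearer at 126 bp, and ranked 217 in replicate 1 and 213 in replicate 2. The sup-35 peak (chromosome III, 11119317 to 11119700) was 283 bp upstream and ranked 1046 in replicate 1 and 362 in replicate 2. The same peak was the nearest to pha-1 (chromosome III, 11131775 to 11136688), 12266 bp upstream. The nearest IDR peaks to sup-36, to ari-1.1, a ubiquitin ligase gene, and to ubc-18, which encodes a ubiquitin-conjugating enzyme, were 16069, 21892 and 80306 bp from their 5′ ends. Bound genes made up 2 of 7 in this list (28.6%, 3.67 to 71.0), which did not pass the test (Fisher's exact test, adjusted exact p = 0.0553). The list did not pass under any of the 9 alternatives either (lowest adjusted exact p = 0.0512), although leaving out the 20 kb around sup-37 and unc-119 could not change it. With each peak given only to its nearest 5′ end, lin-35 was no longer counted and the ratio to other genes fell from 8.33 to 4.55 times. The unbound genes of the list include sup-37, which lies in a stretch where neither replicate listed a region. The list was not tested without this gene.

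The tagged gene itself lay in a stretch with no region in any list. The gene sup-37 (chromosome V, 8786545 to 8792781) had 3 regions within 20 kb in replicate 1, 5 in replicate 2 and 5 in the pooled list, where the median over other protein-coding genes was 13, 12 and 13. Counts as low were found at 1.80%, 6.69% and 5.93% of other genes in these lists, so they were low but not unique. Regions within 20 kb of sup-37 are described next. Of the regions within 20 kb of sup-37, 3, 2 and 3 had their summit inside rpm-1, a neighbouring gene for a ubiquitin ligase of synapse formation, among them the IDR peak of rank 605 (chromosome V, 8811292 to 8811675), whose summit is in a coding exon. Between the summits at 8768560 and 8811450, a distance of 42890 bp that holds sup-37, srx-115, B0507.1, B0507.2, B0507.3 and magu-2, neither replicate listed a summit. At unc-119 (chromosome III, 10902641 to 10908935), the rescue marker of the transgene, 15, 9 and 11 regions lay within 20 kb in replicate 1, replicate 2 and the pooled list, with 2, 1 and 2 inside the gene and none in the IDR list. The best of these ranked 1565 in replicate 1 and 2053 in replicate 2.

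**Figure D4:**
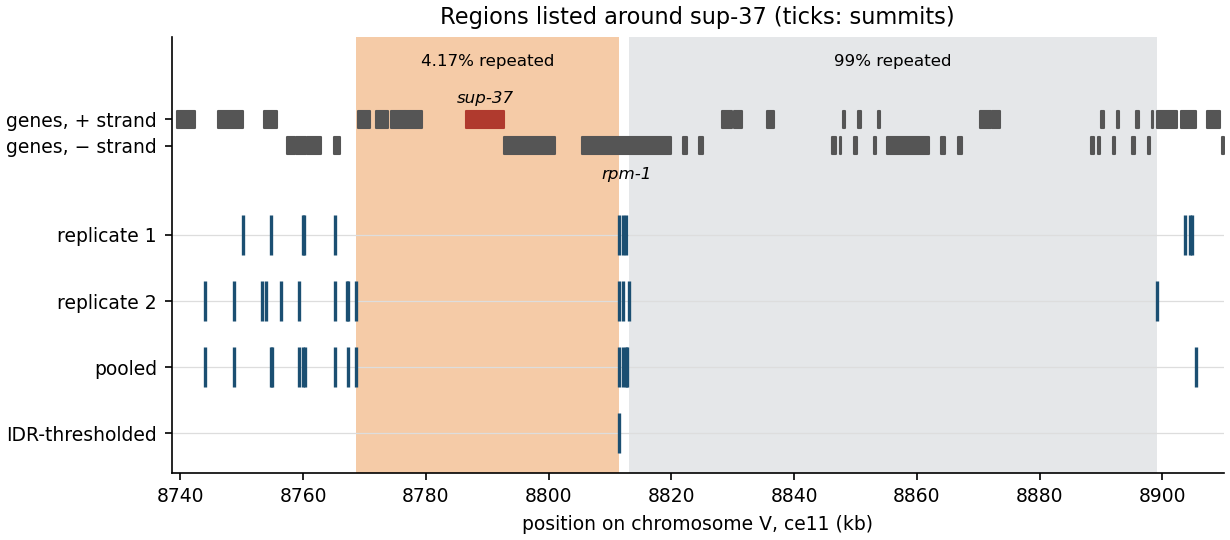
Map of chromosome V around sup-37 (horizontal axis, kb, ce11), with protein-coding genes by strand on top and a tick for the summit of every region in each of the 4 lists. The orange stretch of 42890 bp holds sup-37 and no summit of either replicate, with 4.17% of its 32-mers present elsewhere in the genome, and the grey stretch of 86065 bp next to it is 99.0% repeated.

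Peaks of the tagged SUP-37 were also found at genes for small structural RNAs. Summits within 200 bp of tRNA genes numbered 49 (5.30% of peaks, 3.95 to 6.95) against a mean of 2.70 in shuffles, those near small nucleolar RNA genes 44 against 1.73 and those near small nuclear RNA genes, a class that holds the spliced leader RNA genes here, 18 against 0.540. These are ratios of 18.2, 25.5 and 33.3. Of 18 SL2 RNA genes, whose product is spliced onto downstream genes of operons, 6 had a peak, led by sls-2.4 (rank 5), and of 12 SL1 RNA genes, which lie in a tandem repeat with 5S rRNA genes, none did. Whether a region could have been listed at such repeated genes was not tested. The tRNA gene with the strongest peak was C18A11.t2 (chromosome X, 8036685 to 8036757, rank 134), and the leading snoRNA gene was Y53F4B.47 (rank 22), beside cmtr-1. These genes and the spliced leader genes were picked after their ranks were seen.

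Unclassified noncoding RNA genes had 205 summits nearby against 33.1 in shuffles, and long intergenic RNA genes 12 against 3.03. Fewer summits than in shuffles lay near piRNA genes (4 against 25.5) and pseudogenes (4 against 34.1). Near piRNA genes the count rose to 8 (against 26.6) with replicate 2 alone and to 6 (against 23.7) with replicate 1 alone, and the call was kept. All 7 of these classes lay outside the 1000 shuffles on the stated side and had an adjusted permutation p of 0.00285 over the 10 classes tested. Antisense RNA genes (4 against 1.17, adjusted permutation p = 0.0824), miRNA genes (3 against 1.05, adjusted permutation p = 0.206) and rRNA genes (0 against 0.150, adjusted permutation p = 1) did not pass. With replicate 2 alone, the long intergenic class was no longer called (0.541% of peaks, adjusted permutation p = 0.404) and the antisense class was (0.541%, adjusted permutation p = 0.0200). The long intergenic call was also lost with the stricter list of 462 peaks (0.866%, adjusted permutation p = 0.182) and with IDR peaks in both top lists only (0.865%, adjusted permutation p = 0.148).

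Sequence at the summits differed from that beside them, and GACGCA was the 6-mer with the smallest p. This word, counted on both strands, was present within 50 bp of 178 summits (19.3%) against 1.95% of flanking windows centred 400 bp away (9.89 times, Fisher's exact test, adjusted p = 4.41e-52 over 2080 6-mers). Words overlapping it came with it, namely ACGCAG (7.90 times), CGCAGA (7.07 times) and AGACGC (7.10 times). GAGAGA (27.6% against 6.33%, 4.36 times), AGAGAG (5.20 times) and AGAGAC (5.57 times) were also enriched, and ACGCGC was at 9.85 times. These words are not all separate from GACGCA, since GAGAGAC, AGAGACG, GAGACGC and AGACGCA were among the 10 7-mers with the smallest p and together chain GAGAGA to GACGCA. The other 6-mers among the 10 with the smallest adjusted p were A/T-rich and rarer at summits, AAAATT (15.04% against 42.1%) and AAAAAT (20.996% against 48.6%). In all, 583 6-mers were at least 1.5 times as frequent at summits with an adjusted p under 0.05, and G and C made up 48.7% of bases at summits against 36.3% and 35.3% in the flanks. Against shuffles of the summit windows that keep their dinucleotides, a background chosen after seeing the data, 153 6-mers were called, GACGCA stood at 3.04 times and GAGAGA at 2.32 times, and neither AAAATT nor AAAAAT was rarer any longer.

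**Figure D5:**
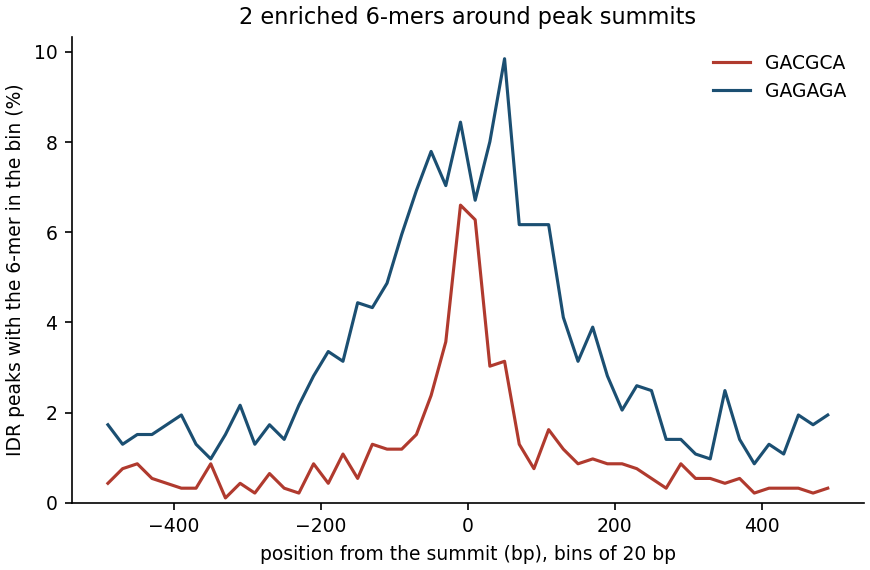
Share of the 924 IDR peaks with GACGCA (red) or GAGAGA (blue) on either strand in each bin of 20 bp (vertical axis, %), by position from the summit (horizontal axis, bp). GACGCA was in 6.602% of peaks in the bin just left of the summit, and GAGAGA had a broader peak of up to 9.85%.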

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

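The alternatives using IDR peaks in both top lists only, dinucleotide-preserving shuffles and genes without small RNA genes at the promoter were chosen after seeing the data. Top-list overlap was 50.9% with summits within 50 bp, 71.0% with the stricter list and 48.9% with lists of 1848 regions, and IDR peaks found in both replicates were 51.5% within 50 bp, 70.8% with the stricter list and 97.7% over the full lists. The rank correlation was 0.650 within 50 bp and 0.648 with the stricter list. The stricter list, which holds fewer peaks, gave 397 genes with a promoter peak and 5 gene lists past the threshold. The central 50% of autosomes, at 57.9% of peaks, passed its test only when the reference share came from length (exact p = 2.39e-05). Enriched words numbered 153 over dinucleotide-preserving shuffles and 996 for 7-mers, of which more exist, and over the shuffles, a background that takes account of base composition, AAAAAT turned to the other side (1.65 times, adjusted exact p = 2.04e-06) while AAAATT no longer differed (1.15 times, adjusted exact p = 0.330). The cause of the other changes was not tested. Promoter share ran from 45.1% to 65.5% and X share from 19.7% to 21.3% over their alternatives, on the same side of the test each time. With each replicate left out in turn, promoter share was 48.8% to 55.2%, genes with a promoter peak 588 to 713, lists past the threshold 7 to 8, noncoding classes past it 7 each time and enriched words 513 to 583. For the 9 lists past the threshold, 62 of 81 checks kept the call, and the lists with calls lost were cell cycle (6 of 9), RNA polymerase II and Mediator (5), mitochondrial ribosomal proteins (4), splicing factors (2), chaperones (1) and oxidative phosphorylation (1). These counts include leaving out the 20 kb around sup-37 and unc-119, which kept all 687 bound genes and so could lose no call. Body wall muscle, heterochronic genes, autophagy and the proteasome passed under 3, 2, 2 and 1 of their 9 alternatives. Depth is unknown, so what more reads would add was not tested.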

Other observations

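Tests chosen after the result was seen were those of GACGCA and GAGAGA between kinds of peak and without shared bases, of sequence with another copy in the reference, of transgene copies in the control libraries and of base composition.

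GACGCA and GAGAGA differed in opposite directions between promoter and other SUP-37 peaks. GACGCA was at 22.7% of promoter summits and 14.98% of other summits (odds ratio 1.67, Fisher's exact test, adjusted p = 0.00872 over 8 comparisons), while GAGAGA was at 20.2% and 36.7% (odds ratio 0.436, adjusted exact p = 2.07e-07). At the 110 summits near tRNA, snRNA or snoRNA genes GACGCA was nearly missing, with 3 (2.73%) against 21.5% elsewhere (odds ratio 0.102, adjusted exact p = 4.27e-07), and GAGAGA was at 18.2% against 28.9% (adjusted exact p = 0.0276). On the X chromosome GACGCA was at 13.0% of summits against 20.9% on autosomes (adjusted exact p = 0.0270), and for GAGAGA the values were 24.4% and 28.5% (adjusted exact p = 0.318). Peaks in both top lists held GACGCA at 21.5% and the others at 15.6% (adjusted exact p = 0.0416), and for GAGAGA the values were 27.3% and 28.0% (adjusted exact p = 0.820).

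A hypothesis written before the test was that GACGCA and GAGAGA belong to separate sets of peaks, which would make them avoid each other. Instead 69 peaks held both, and GAGAGA was in 38.8% of peaks with GACGCA against 24.9% of those without it (odds ratio 1.91, Fisher's exact test p = 3.64e-04), which goes against the hypothesis. In 14 of the 69 the words only occurred sharing bases, as parts of a longer word. Counting GAGAGA only where it shared no base with GACGCA, the values were 30.9% and 24.9% (odds ratio 1.35, 95% exact interval 0.921 to 1.95, exact p = 0.107), so that the words did not avoid each other in either count, while the excess passed the threshold only with shared bases included. No biological explanation was tested.

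Neither replicate listed a region over 42.9 kb around sup-37, the gene that was tagged. Extra transgene DNA in the precipitated libraries would add regions if the controls lacked it, but the higher count within 20 kb was 5 against a median of 12 in that replicate. If the controls carried the transgene too, this count cannot decide, because regions were called against them. Repeats are argued against by 24.9% of soft-masked bases (median of other gene-centred windows 30.7%) and 4.17% of 32-mers with another copy (median 5.38%). The other 5 stretches at least as long without a region had 52.3% to 99.3% of their 32-mers repeated, so this was the only one of the 6 made mostly of unique sequence. A candidate explanation is that the control libraries carried the same transgene in several copies and so raised the background there; unc-119, the marker, had at least 1 region inside the gene in each replicate, which would go against it if the marker were the worm's full gene, but the labels do not say which part or which species' copy was used. This stays open because the control data were not analysed here, and no biological explanation was tested.

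The promoter share of IDR peaks might come from promoter DNA that is over-represented in any sheared chromatin. A test fixed beforehand compared pooled regions ranked below 15000, which lay at promoters in 21.4% of cases (20.8 to 22.1), with the IDR peaks at 55.2%. It decides nothing, because regions are ranked by signal and over-represented promoter DNA would itself rank high and leave the bottom of the list. The explanation stays open, as the control data were not analysed here, and no biological explanation was tested.

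Base composition could produce many of the enriched words, since summits are richer in G and C than their flanks. Over shuffles that keep dinucleotides, 118 of the 583 words remained enriched (20.2%, 17.1 to 23.7), so for the set as a whole composition can be neither excluded nor taken as enough. All 8 enriched words among those named stayed enriched, the lowest at 1.62 times (ACGCGC), which argues against dinucleotide composition alone as their whole cause. Several of the 8 overlap each other, so they are not separate tests. AAAAAT, which was rarer at summits than in flanks, stood at 1.65 times over the same shuffles. Low ratios such as that of ACGCGC therefore say little, and longer repeats, which the shuffles do not keep, were not tested. No biological explanation was tested.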
